A study of Mus musculus with 6 samples.

How the data were processed

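RNA from pooled cerebellar nuclei of trained and sham-operated mice was measured on 6 one-colour Affymetrix arrays, 1 per condition on each of 3 array types, with biotin-labelled cRNA, per the labels' protocols. Groups and array types were read from the sample titles. Whether the 3 arrays of a condition were hybridised with RNA of the same pool is not given in the sources used here. The deposited value tables hold 1 value per probe set and array, taken here as log2 signal because they reach 13.4 at most, a range that the logarithm to base 2 of scanner intensities gives. The authors' summary and normalization method is not given in the sources used here, so the centring of the deposited log2 values is known only from their medians, which differed between the arrays of a type by -0.024, -0.0035 and -0.030 for A, B and C.

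Each trained array was compared only with the sham array of its own type. Both arrays of a type were brought to the same median. The design, fixed before the data were examined, set this for values on a log scale and a trimmed mean otherwise; the alternatives, main comparisons, gene lists and rule for named genes were fixed at the same time. The 66 control probe sets of each type were then left out. A floor was set as the lower edge of the lowest of 20 brightness bins from which that bin and every brighter one had a robust SD of the log2 ratio under 0.5. Every bin met this, so the floor lay at the dim end and 36692 of 36701 probe sets counted as measured. It therefore removes almost no unexpressed probe set, and a floor at the brightest bacterial or yeast control was added after the data were seen. These controls, also called non-mouse controls here, are the Dap, Lys, Phe, Thr, Trp and yeast probe sets, without the brighter BioB, BioC, BioDn and Cre spikes. A single Phe probe set fixed that floor on each type, at 4.93, 5.08 and 5.13 on A, B and C. The next brightest control reached 2.99, 3.56 and 3.47, so the floor is strict.

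Probe sets were named through the platform annotation, with symbols updated through Entrez identifiers to the GRCm38.p6 gene table, which changed 0 symbols. Of 36701 probe sets, 29131 named 1 gene, 724 several and 6846 none, and only the first were used for genes. A gene's value was the mean log2 ratio, trained minus sham, of its measured probe sets, for 15965 genes. Genes were named in the text by size. The main rule took the 15 largest in each direction among genes whose probe sets all differed the same way and whose brighter value was at least 2-fold over the floor. In each list, up to 2 members at either end could also be named. Rules for genes with several probe sets all at least 2-fold different, and for genes seen on 1 array only, named 0 genes. Other genes are said to have been chosen after their values were seen.

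There were 24 gene lists with 913 different measured genes. A list's median was placed among 10000 random lists of the same size drawn from the same 20 expression bins, and a list was called apart when its percentile lay in the outer 2.5 percent at either end and at least 5 of its genes were measured. With 1 array per condition and type there is no test, no p-value and no standard error, and the number of arrays limits the precision.

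The steps were tested on simulated data, made from the real signal levels and the spread of the real ratios in each brightness bin, in 20 repeats with 200 changed genes each among 15965 genes. Of probe sets simulated at 2-fold, 48.4 percent passed the 2-fold rule, as did 0.331 percent of those at 1.5-fold and 100 percent of those at 3-fold and 4-fold. Of 726473 unchanged or slightly shifted probe sets, 0 passed. The simulated noise was normal with the robust SD of each bin, 0.19 at most, so that 0 was nearly fixed in advance. Longer tails of the real ratios were not simulated, so it does not exclude noise behind a real 2-fold value. Lists of 30 genes shifted by 0.05 were called in 9 of 20 repeats, by 0.1 in 19 and by 0.15 in 20, and 18 of 480 unchanged lists were called. The simulation holds array noise alone and not the spread between pools or animals.

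Quality was checked on the control probe sets. The ratio of 3' to 5' signal of Gapdh was 1.12 in sham and 1.08 in trained tissue on type A, 1.36 and 1.10 on B, and 1.07 and 1.03 on C. For beta-actin it was 1.65 and 1.62, 1.92 and 2.04, and 1.67 and 1.74. Other controls differed more. The ratio of pyruvate carboxylase was 1.84 and 2.17 on A, that of 18S rRNA 2.76 and 3.18 on A and 2.52 and 3.14 on B, and that of the transferrin receptor 5.41 and 4.30 on C. Bacterial and yeast controls were lower in trained tissue in 17 of 19 probe sets on A, 9 of 19 on B and 9 of 19 on C, and antisense controls in 12 of 15 on A, 14 of 15 on B and 6 of 15 on C. Alternatives covered no scaling, quantile and loess scaling, floors 1 log2 unit lower and higher, no filter, plain probe set names only, type A only, and the brightest probe set per gene. Types B and C alone, the control-based floor, both together, and the 1.5-fold counts were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.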

Results

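After eyeblink conditioning, a list of glucocorticoid-responsive and stress genes stood out in the cerebellar nuclei of trained mice when set against sham-operated mice. Over 2 of the 3 array types alone they stood apart as a group only in bright probe sets. Hormone levels were not part of the data, and an error of the type A arrays or a difference in time of day stays open. Sgk1, Nfkbia, Ddit4 and Klf15, all known targets of the glucocorticoid receptor or of stress signalling, were among the transcripts with the highest trained over sham ratios. Genes of mitochondrial energy production were slightly higher as a group in the main setting. Over 2 of the 3 array types alone they lay within the range of matched random lists, with or without dim probe sets. Markers of the neighbouring brainstem, most of them dim, were slightly lower. Calb1 and Car8, a pair of calcium-handling genes typical of Purkinje cells, were also higher after training. Lists of synaptic, ion channel and activity-induced genes lay within the range of matched random lists in the main setting, some of them near its edge or outside it in alternatives.

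Eyeblink conditioning teaches an animal to close its eyelid at a tone that predicts a shock near the eye, and the memory depends on the cerebellum and its deep nuclei. The comparison asks which transcripts in those nuclei differ once mice have been trained. Tissue came from male C57BL/6 mice of 11 to 18 weeks, from the deep nuclei around the anterior interpositus on the side of the wired eyelid. Nuclei were pooled by condition, 10 to 15 to a pool, and collected 10 to 30 min from sacrifice, and whether the arrays of a condition shared a pool is not given. Trained mice had 3 days of recovery and 3 days of pairing a 352 ms tone of 1 kHz at 83 to 85 dB with a 100 ms periorbital shock of 100 kHz that began 252 ms after tone onset. Sham mice had the surgery and received no stimuli, so a difference between the conditions covers pairing, tone, shock and handling together. Days from surgery to sampling are not given for sham mice in the sources used here. Time since surgery, collection delay and pool therefore cannot be told apart from training either.

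The data were 6 arrays, 1 trained and 1 sham array of each of 3 array types, called A, B and C here, which carry different probe sets. There was 1 array per condition and type, so no difference has a replicate check, and all values are sizes of a difference on these arrays. After control probe sets were left out, the types held 12422, 12411 and 11868 probe sets. The trained and sham array of a type were close, with Pearson correlations across probe sets of 0.997 for A, 0.996 for B and 0.995 for C, where probe sets are not independent replicates. The robust SD of the log2 ratio was 0.16, 0.15 and 0.16.

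Differences of 2-fold were rare. Of 36692 measured probe sets, 5 were at least 2-fold higher after training and 0 were at least 2-fold lower, against 2 lower in the values as deposited, without scaling. At the lower limit of 1.5-fold, set after the data were seen, 80 were higher and 32 lower, against 27 and 8 among probe sets brighter than the bacterial and yeast controls and 11 lower with plain probe set names. Sgk1, a kinase that serum and glucocorticoids induce and that regulates ion channels and transporters, stood far above the others, with a log2 signal of 6.43 in sham and 9.003 in trained tissue on array type A, a 5.95-fold ratio. Its probe set on array type C was dim, at 2.45 and 2.23, and did not share that difference. The other 4 were Meg3, Hspa1b, Cebpd and Polr3e, with log2 ratios of 1.18, 1.13, 1.07 and 1.03. Meg3 is a long noncoding RNA kept in the nucleus, and its 9 probe sets ranged from -0.29 to 1.18. Cebpd is a transcription factor of acute stress and inflammation. Its sham value of 4.21 lay under the brightest bacterial or yeast control of type A at 4.93, but above the next brightest at 2.99. Its 1.07 may therefore be limited by background, which was not shown, and a second, dimmer probe set was at 0.11. Meg3 was named here after its values were seen.

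**Figure D1:**
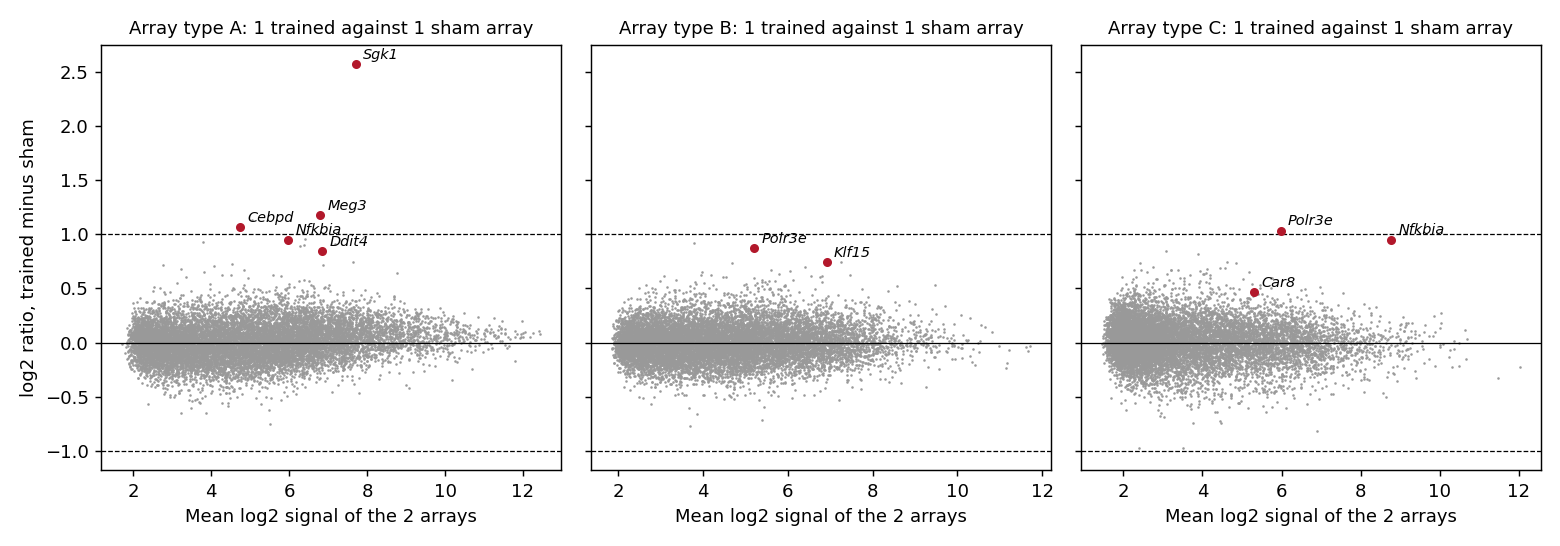
Log2 ratio of each measured probe set (trained minus sham, vertical axis) against the mean log2 signal of both arrays (horizontal axis), 1 panel per array type, with dashed lines at 2-fold and selected genes marked in red. Sgk1 on array type A lies at 2.57, and 0 probe sets lie below the lower line.

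Among genes whose probe sets all differed in the same direction, the 15 with the largest higher values ran from Hspa1b at 1.13 to Zfp280d at 0.65. Nfkbia encodes the inhibitor that holds NF-kB in the cytoplasm, and its 3 probe sets on types A and C lay between 0.91 and 0.95. Ddit4, a stress-induced inhibitor of mTOR signalling, was higher by 0.84, and Klf15, a transcription factor under glucocorticoid control, by 0.74. Polr3e, a subunit of RNA polymerase III, averaged 0.78 over 3 probe sets, of which that on type B was dim in sham. Rsrp1 encodes an arginine- and serine-rich protein and Clk1 a kinase of splicing factors, and they were higher by 0.74 and 0.71. Wac, an adaptor in histone ubiquitination, was higher by 0.73. Abhd17c, which removes palmitate from synaptic proteins, and Frmd4a, a scaffold of cell polarity, were higher by 0.73 and 0.67. Of the 15 genes, 9 had a probe set brighter than every bacterial or yeast control on both arrays, and 4 had more than 1 probe set. Hspa1b, Abhd17c, Wac, Amy1, Ccdc185 and Zfp280d did not pass these controls on both arrays. The 1.13 of Hspa1b is thus a ratio over a sham value of 4.49 that was not above all of them.

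Among the genes named by the main rule, those lower after training were dimmer and less secure. The 15 with the largest lower values each had 1 probe set, and 3 of them, Zfp882, Cerox1 and Etv2, were brighter than the bacterial and yeast controls on both arrays. Cerox1, a noncoding RNA that regulates complex I of the respiratory chain, was at -0.57, and Zfp882, a zinc finger gene, at -0.60. Kdm1a, a histone demethylase of neuronal gene repression, was at -0.51, Gpr45, an orphan receptor, at -0.57 and the noncoding RNA Sox2ot at -0.56. The lowest value was that of 4930404I05Rik, an uncharacterised gene, at -0.74.

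The glucocorticoid-responsive and stress genes stood apart from the rest as a group. The list's 30 measured genes had a median log2 ratio of 0.14, at percentile 99.99 of 10000 random lists matched on expression, a percentile given as a description of these arrays. Of the 30 genes, 22 were higher and 4 were at least 1.5-fold higher, which were Sgk1, Nfkbia, Ddit4 and Cebpd, the last on probe sets that did not pass the bacterial and yeast controls on both arrays. Errfi1, an inhibitor of EGF receptor signalling, was higher by 0.43, Klf9, a hormone-responsive transcription factor, by 0.42, Arrdc2, an arrestin-like adaptor, by 0.41, and Fkbp5, a cochaperone that dampens the glucocorticoid receptor, by 0.39. Errfi1, Arrdc2 and Fkbp5 were picked out after their values were seen. The list was not uniform, since Tsc22d3, a classic glucocorticoid target also chosen afterwards, was at -0.088 on a dim probe set and Angptl4, a lipid regulator, at -0.15. Over the probe sets of types B and C alone, dim ones included, the median was 0.0225, at percentile 73.1, and over the 8 genes with probe sets there brighter than the bacterial and yeast controls it was 0.17, at percentile 99.7.

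**Figure D2:**
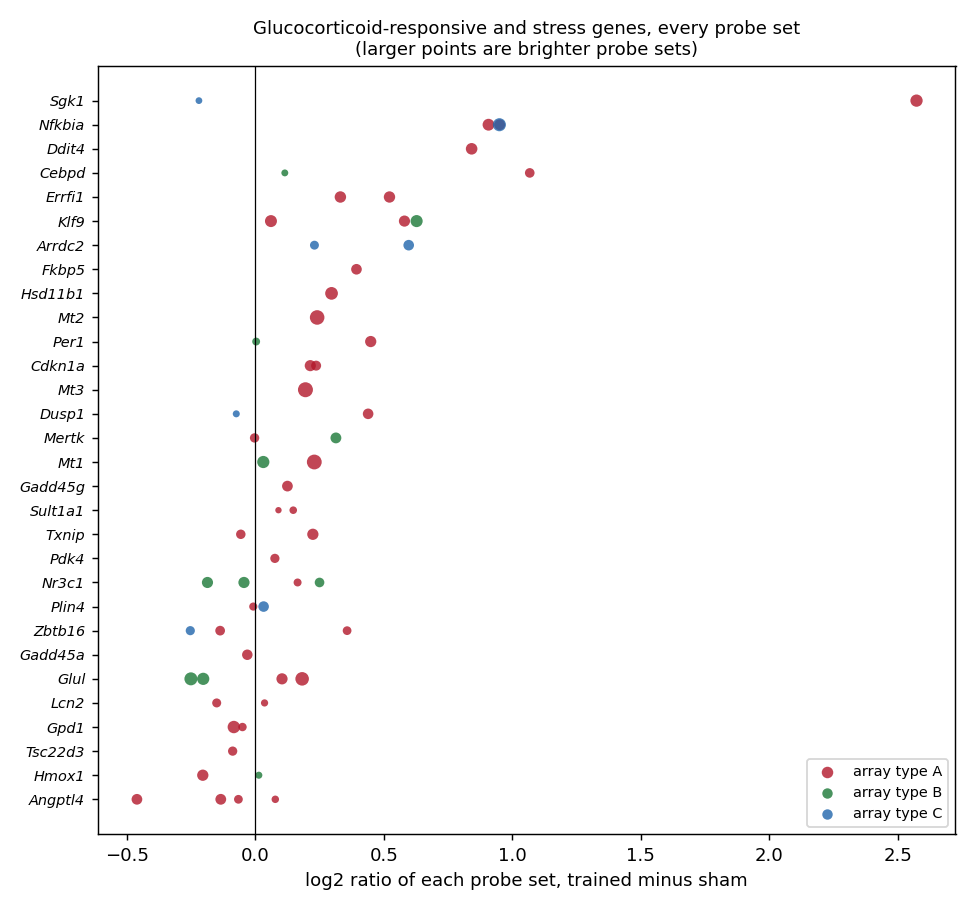
Log2 ratio (trained minus sham) of every measured probe set of the 30 glucocorticoid-responsive and stress genes, coloured by array type and sized by brightness. Nfkbia lies between 0.91 and 0.95 on types A and C, while the dim type C probe set of Sgk1 lies at -0.22.

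Nuclear-encoded genes of oxidative phosphorylation formed the other group above matched lists. Their 65 genes had a median of 0.0945, at percentile 99.99, and 50 of them were higher. On type A, however, bright probe sets of all kinds were higher, with medians of 0.054 to 0.074 in brightness bins 17 to 20. The random lists were matched on brightness but not on array type. Uqcrb of complex III and Sdhd of complex II were highest, at 0.42 and 0.38, while Ndufb7 and Ndufa1 of complex I were lower at -0.18 and -0.30, the latter on dim probe sets. The shift was small, was 0.0385 after a loess correction for brightness, and over types B and C alone was 0.0242, within the matched range at percentile 81.6. Over the probe sets of types B and C brighter than the bacterial and yeast controls it reversed to -0.0296, at percentile 23.2. Markers of neighbouring brainstem nuclei, the only list below matched lists, had a median of -0.087 over 21 genes, at percentile 0.775, and lay within the range with the brightest probe set per gene (3.24) and on types B and C alone (7.92). Of these, 14 were lower, among them Hoxb6 and Lhx3, patterning factors of the hindbrain and spinal cord, at -0.32 and -0.26. Only 3 of the 21 genes were brighter than the bacterial and yeast controls, and all of these were lower, with a median of -0.14. Antisense control probe sets had medians of -0.15 on type A, -0.088 on B and 0.035 on C. If the genes of each list varied independently, 1.2 of 24 lists would lie outside the central range by chance, and 3 did. Genes of a list that vary together would raise that 1.2, so the 3 are not shown to be an excess.

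**Figure D3:**
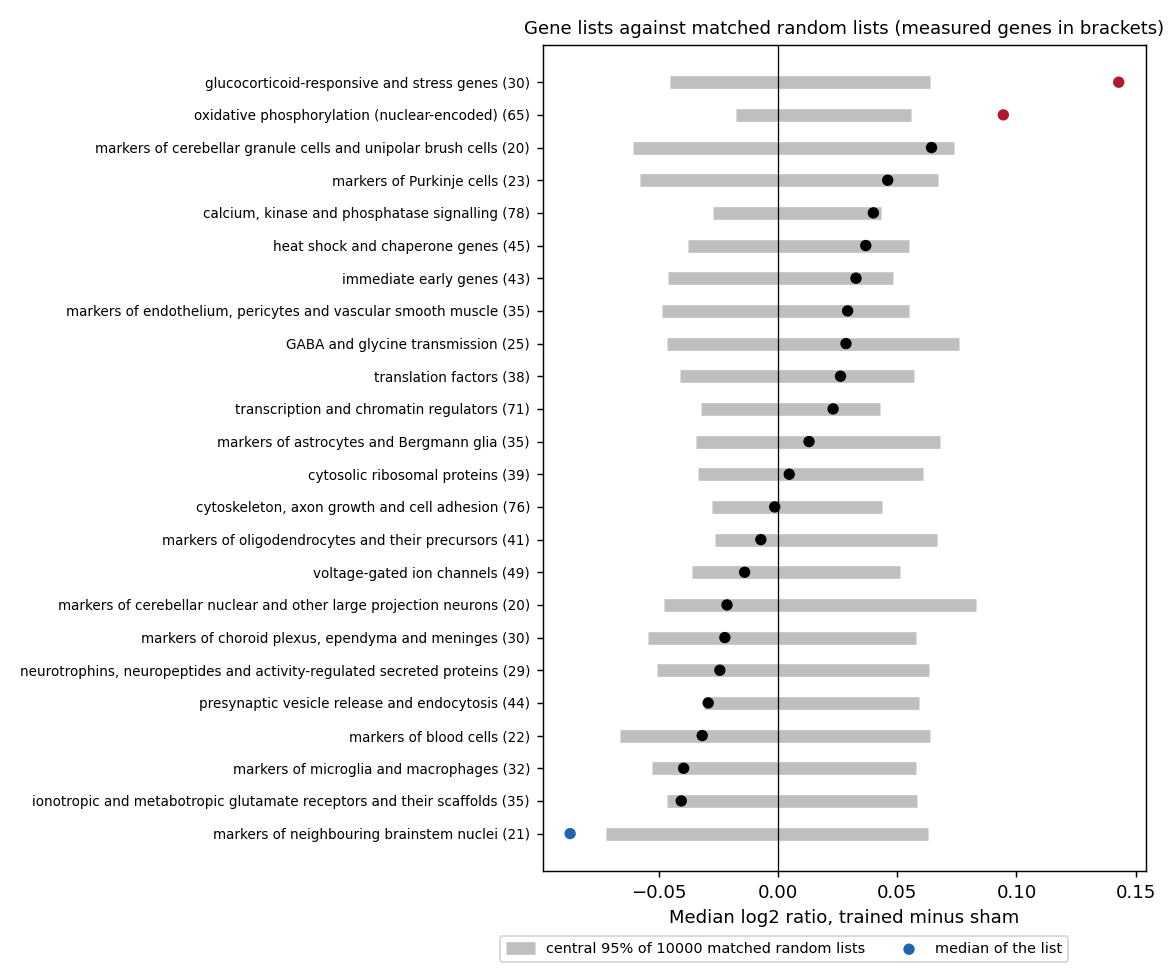
Median log2 ratio (trained minus sham, horizontal axis) of each of 24 gene lists as a point, over a grey bar for the central range of 10000 matched random lists, with the number of measured genes in brackets. The glucocorticoid-responsive list at 0.14 and oxidative phosphorylation at 0.0945 lie to the right of their bars, and the brainstem markers at -0.087 to the left.

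Genes that neuronal activity switches on within minutes lay within the matched range in the main setting. The 43 immediate early genes had a median of 0.033, at percentile 90.2, and were above it on type A alone (98.7), with a floor 1 log2 unit higher (98.9) and with plain probe set names (98.2). Their highest members were Cebpd and Klf9, which the stress list also holds. Fos, Egr1, Junb and Arc, activity markers chosen afterwards, were at 0.15, 0.097, -0.012 and -0.15, and the probe sets of Fos and Arc were dim. Fosb, on a dim probe set, and Atf3 were lower, both at -0.26. Heat shock and chaperone genes lay at 0.037, percentile 88.2, despite Hspa1b at 1.13. Its near-identical neighbour Hspa1a was at 0.90 on type A and at 0.0205 on a dim probe set of type C, and probe sets of such close copies were not shown to be specific.

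The lists that describe synaptic function lay within the matched range in the main setting. Glutamate receptors and scaffolds had a median of -0.041, percentile 4.15, with Gria3 of the AMPA receptor at 0.23 and the scaffold genes Dlg4 and Dlg3 at -0.25 and -0.26. Genes of vesicle release and endocytosis were at -0.029, percentile 3.15, and voltage-gated channels at -0.014, percentile 16.1. GABA and glycine transmission was at 0.0285, percentile 70.6, and at 0.13, percentile 99.7, over probe sets brighter than the bacterial and yeast controls. Voltage-gated channels and secreted or neuropeptide genes were below the range in 2 of 12 alternatives each, and vesicle release in 1. Calcium, kinase and phosphatase signalling was at 0.040, percentile 96.0, led by Ryr2, a calcium release channel, at 0.49. The secreted and neuropeptide list was at -0.024, percentile 14.4, and the cytoskeleton and adhesion list at percentile 29.2. Transcription and chromatin regulators lay at percentile 83.0, translation factors at 77.8 and cytosolic ribosomal proteins at 36.7.

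Markers of cell types described how alike the pools were in tissue. Purkinje cell markers had a median of 0.046, percentile 90.4 (98.3 and above the range with the brightest probe set per gene), and 2 of 23 were at least 1.5-fold higher. These were Calb1, a calcium buffer, at 0.73 over 3 probe sets on types A and B, and Car8, a regulator of the IP3 receptor, at 0.68 over 2 probe sets on types A and C. Only their type A probe sets, at 0.96 and 0.89, passed the bacterial and yeast controls on both arrays. The glutamate transporter gene Slc1a6 was at 0.45, and Pcp2, a marker confined largely to Purkinje cells, at 0.033, with a sign that turned in some alternatives. Both Slc1a6 and Pcp2 were picked afterwards. Granule and unipolar brush cell markers were at 0.064, percentile 95.3 (above the range at 97.9 under quantile and under loess scaling and at 99.6, with a median of 0.12, on types B and C alone, but at 44.8 with the control floor), with Fat2 at 0.49, Gabra6 at 0.35 and Cbln1 at -0.14. Markers of nuclear and other large projection neurons were at -0.021, percentile 12.5, with the fast potassium channel gene Kcnc1 at -0.23 and the heavy neurofilament gene Nefh at 0.17. Astrocytes lay at percentile 48.7 (2.12 and below the range on types B and C alone), oligodendrocytes at 14.2, microglia at 6.56, endothelium and pericytes at 83.4, choroid plexus and meninges at 19.1 and blood cells at 16.4. Ttr, a choroid plexus transcript, was higher at 0.50 and Cldn5 of endothelial junctions lower at -0.38.

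Probe sets of one gene gave a further check on single values. Over 7644 genes with at least 2 probe sets, the log2 ratios of the brightest and next brightest probe set correlated weakly across genes, with Pearson 0.056 and Spearman 0.0555. Of 27 genes whose brightest probe set differed by at least 1.5-fold, 17 had the next one in the same direction. Over all 7644 genes the share in the same direction was 52.3 percent. Above the bacterial and yeast controls the correlations were 0.13 and 0.115 over 2147 genes. There, 5 of 6 such genes had the next one in the same direction, against 54.0 percent of all 2147. Ddit4, Klf15 and Clk1 rest on 1 probe set each, and Calb1 and Car8 on 1 each above those controls, whereas Nfkbia was higher in 3 such probe sets and Polr3e in 2.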

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

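Tests added after the data were seen are the 1.5-fold counts, the floor at the non-mouse controls, pairs B and C only, and these last combined. Over all alternatives, 828 values of single genes moved by less than a set limit and 4 by more. The limit was the SD of a gene's own probe sets, or for 1 probe set the mean robust SD of the ratios. It was a loose limit, since Sgk1, with an SD of 1.97, changed sign within it. Genes with 1 probe set had the same reading in most alternatives, so the 828 say little about robustness. Of list medians, 256 stayed within the matched spread, 23 moved and 1 reversed. Of counts, 49 stayed within 1.5 times and 13 did not. The 5 probe sets at least 2-fold higher became 3 with the control floor and 1 in pairs B and C only, where fewer probe sets were compared; 0 lower became 2 in the values as deposited. At 1.5-fold, the 80 higher became 26 in pair A only and 27 with the control floor, and the 32 lower became 11 with plain probe sets, 6 in pair A and 8 with the control floor. Lists above numbered 4 with plain probe sets and 1 in pairs B and C; lists below numbered 3 with plain probe sets, 3 in pair A and 0 with the brightest probe set, where the brainstem markers lay within the range at percentile 3.24, as they did in pairs B and C at 7.92. Calls held in 9 of 12 alternatives for immediate early genes and granule cell markers, which were above in the rest, in 10 of 12 for neuropeptides and voltage-gated channels, below in the rest, in 10 of 12 for oxidative phosphorylation, in 10 of 11 for Purkinje cell markers, and in 11 of 12 for GABA and glycine, vesicle release, heat shock and astrocyte lists; the other 12 lists apart from brainstem and glucocorticoid genes kept theirs in all alternatives that gave a call. The glucocorticoid list stayed above in 11 of 12 alternatives, at 0.22 with the brightest probe set and 0.23 with the control floor, and was within at 0.0225 in pairs B and C. Oxidative phosphorylation was 0.0431 under quantile and 0.0385 under loess scaling, 0.0242 in pairs B and C, and -0.0296, reversed, in pairs B and C with the control floor. In pairs B and C only, neuropeptides were 0.0336, heat shock genes -0.0135 and astrocyte markers -0.0730; with the control floor as well, immediate early genes were -0.0406, neuropeptides 0.0393, GABA and glycine genes 0.11, heat shock genes -0.0801, astrocytes -0.0619 and endothelium 0.0930. With the control floor alone GABA and glycine genes were 0.13 and translation factors 0.0784. In pair A only, voltage-gated channels were -0.0640, oligodendrocyte markers 0.0481 and cytoskeletal genes 0.0392; loess put oligodendrocytes at -0.0556, and the brightest probe set put glutamate receptors at 0.0277 and cytoskeletal genes at 0.0448. The correlation between probe sets of a gene was 0.13 with the control floor. Beyond fewer probe sets or arrays, the cause was not tested. Sgk1 changed sign in pairs B and C, where only its dim probe set remained. Ratios of probe sets no brighter than the non-mouse controls may be limited by background, although 1 Phe probe set fixed that floor on each type. No paired analysis was possible because each comparison holds 1 array per condition.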

Other observations

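Of the tests below, those of brightness bias and of NF-kB targets for the glucocorticoid list, of time of day, and of cerebellar cortex and Purkinje cells, and the limits to probe sets above the non-mouse controls in the NF-kB, Purkinje and unnamed probe set tests, with the bound and resampling of the NF-kB test, were chosen only after the result was seen. The lists of clock genes, NF-kB targets and splicing-related RNAs were drawn up after the report's values were seen. Bootstrap limits below come from resampling the genes or probe sets of a list, as if they were independent. They hold no spread between pools or arrays, so what argues against a cause does so for these arrays only.

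The glucocorticoid-responsive list was higher after training. A loess correction for brightness left its median at 0.13, against 0.14 before, which argues against brightness bias as the whole cause. The percentile after loess was 100, but it adds little, since the random lists were themselves matched on brightness. NF-kB targets other than Nfkbia had a median of -0.086 over 26 genes, but most did not pass the non-mouse controls. The 8 above the non-mouse controls had a median of -0.11 with a bootstrap upper limit of 0.072, under 0.12, 50 percent of the glucocorticoid-responsive median above the same controls, and the difference from that bound, with both resampled, had an upper limit of -0.048. As a set these 8 did not rise by that much, though Csf1 was at 0.33 and the genes were few. Moreover, 50 percent of the median over all probe sets, 0.071, lay at about the upper limit. Inflammatory targets such as Il6, Il1b, Ccl2 and Tnf, at 2.11, 2.92, 2.41 and 4.35 in sham, fell under that floor. The 8 therefore cannot decide on inflammatory NF-kB signalling, which stays open. An error of the pair A arrays stays open. Among 8 genes brighter than the non-mouse controls in pairs B and C the median was at percentile 99.8, in a separate draw of random lists from that in the Results. But its bootstrap interval from -0.10 to 0.63 was wide, and without that floor the percentile was 73.1. A difference in time of day cannot be told apart from training with these genes, since E-box clock genes minus those of opposite phase differed by 0.13, percentile 92.2, while the E-box list alone, with Dbp at 0.33 and Hlf at 0.28, lay at percentile 99.6. Stress of shock and handling is a candidate explanation beside learning, and with no stimulus-only control analysed here it was not tested.

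Of the lists of Purkinje, granule, nuclear and brainstem markers only the last was outside the matched range in the main setting. Granule cell markers were above it under quantile and loess scaling and in pairs B and C (0.12, percentile 99.6), Purkinje cell markers with the brightest probe set (98.3), and brainstem markers within it in pairs B and C (7.92), so a dissection with more cortex in the trained pools cannot be told apart from none. Pooled by the direction already seen, 42 cortex markers exceeded 40 nuclear and brainstem markers by 0.096, at percentile 99.8. In 8 of 9 alternatives the percentile was 97.96 or higher, with 0.14 and 99.7 in pairs B and C, and in bright probe sets of these pairs it was 81.2, at 0.072, but lists pooled in that way restate what prompted them. Whether more Purkinje cells lie behind Calb1 and Car8 cannot be decided from these lists. The other 21 Purkinje cell markers had a median of 0.038, with 14 higher and a bootstrap upper limit of 0.085. That lay under the 0.35 that would be 50 percent of the mean of Calb1 and Car8. But some markers are shared with other cells, such as Pvalb, also on the list of nuclear neurons, and would dilute such a rise. Ppp1r17 was at 0.31, and of 2 dim markers Cacna1g was at 0.33 and Lhx1 lowest at -0.19. The 11 of these 21 above the non-mouse controls gave 0.070, upper limit 0.17, with 10 higher and values that ranged widely, such as Slc1a6 at 0.45 and Pcp2 at 0.033. More Purkinje cells and a change within cells both stay open.

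Rsrp1 and Clk1, both related to splicing, were among the genes with the largest higher values, and single probe sets of the nuclear RNA Meg3 were high as well, though its mean over all probe sets was 0.33. They prompted a list of other such RNAs, whose own values had not been seen when it was written. Its 56 measured genes had a median of 0.11, at percentile 100 of matched lists, and 48 were higher, including Snhg12 at 0.44, Neat1 at 0.41, Ddx5 at 0.30, Miat at 0.29 and Luc7l2 at 0.25, with Snhg3 at -0.49 as the largest exception. Snhg12 and Neat1 were dim in sham, at 4.74 and 3.73, and the probe sets of Luc7l2 averaged 4.09, under the brightest non-mouse controls. The list's median was not computed above those controls. After loess the median was 0.10, against 0.11 before, which argues against brightness bias as the whole cause. The percentile after loess was 100, but the random lists were themselves matched on brightness, so it adds little. Probe sets naming no gene differed from matched ones by 0.0006, or -0.0075 over those above the non-mouse controls, under a bound of 0.056. They were not shown to lie in introns or between genes, so they cannot decide on more unspliced RNA or genomic DNA. An error of the pair A arrays stays open, since pairs B and C alone gave percentile 99.8 with a bootstrap interval of the median from 0.017 to 0.10. A shared shift of this size does not account for Rsrp1 and Clk1, since its bootstrap upper limit of 0.13 lay under the bound of 0.36, set before the test as 50 percent of the smallest of Rsrp1, Clk1 and Wac, which was Clk1. Wac was dim and is not a splicing gene. Meg3 was left out of that bound, and 50 percent of its value, 0.17, lay nearer the limit; a small shift of the list as a whole met the other outcome set before the test and stays a hypothesis.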
